A study of Mus musculus with 6 samples.

How the data were processed

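Messenger RNA was profiled in PAM212 cells, a line labelled as mouse keratinocytes, grown in DMEM with 10% fetal bovine serum. The 6 samples fall into 3 libraries of cells infected with a lentivirus carrying the mouse miR-28-3p gene and 3 control libraries of PAM212 cells. The treatment label of the controls reads as untreated, while their titles use an abbreviation that usually stands for negative control, so whether the control cells carried an empty vector is not given in the sources used here. The series title names keratinocytes and its design line names melanocytes, and the cell line and source labels of every sample name PAM212 and keratinocytes, which was followed here. Polyadenylated RNA was extracted with Trizol and made into libraries with the Illumina TruSeq kit. The labels do not say whether the 3 libraries of a group are separate cultures or technical repeats of one RNA, so the replicate error may be technical only.

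The authors deposited a table with read counts per gene in each library, which per the file headers are raw counts, and the whole numbers in it sum to between 14309898 and 16383374 per library. The same table holds FPKM values, and per the file headers each is a count scaled by gene length and library size. Dividing each count by the deposited gene length and by the column total gave every nonzero deposited FPKM to within 0.001%. A table of differential expression by the authors holds a log2 fold change and an adjusted p-value for 15710 genes, with infinite log2 values where the mean of a group is 0. The deposited read statistics give raw and trimmed read counts and the percent of reads kept, and the percent of bases at or above the Q30 quality score. HISAT2, HTSeq and DESeq stand in the submitters' processing notes without versions, order or parameters. The notes name the mouse build mm9, but 21617 of 21936 listed genes have the same chromosome, start and end as in GENCODE release 21 for the mouse build GRCm38, and 21817 were matched by gene identifier. Coordinates here are therefore those of GRCm38. A matching symbol was found for 21446 genes, and 21780 are protein coding in that release. The table lists 0 microRNA genes and 15710 genes with any count. The strand setting, the pairing of reads and the treatment of reads shared between paralogs are not given in the sources used here, and reads of near-identical gene copies may have been dropped or shared at that step.

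Counts were compared between the groups with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 11809. Library sizes were scaled with TMM, and the robust quasi-likelihood F test was used with an adjusted p (Benjamini-Hochberg) under 0.05 as the threshold. Levels are CPM, the share of a library's counts scaled with TMM, given as the mean ± SD over n = 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the normal deviate of its p. It is thus derived from the test and does not measure the spread between replicates. A gene at 0 in a group was set against a floor of 3 counts summed over the group, and a gene with 1 to 3 counts in a group was given the ratio of group CPM with an exact 95% interval. In a single library 3 counts equal 0.183 to 0.21 CPM. Intervals and floors cover counting error only, since reads made by PCR are not independent molecules.

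The 34 gene lists, the tests and the rule for naming genes were chosen before the data were examined. The rule takes genes with an adjusted p under 0.05, at least 5 CPM in the higher group and every overexpression library on the same side of every control library. From these, unnamed gene models left out, the 10 with the largest rise and the 10 with the largest fall are named. It adds the genes of the miR-28 locus, up to 4 members of each list with the smallest p, and the 5 genes with the smallest p among those that fell and have a miR-28-3p site. Not every gene the rule takes is described. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 29 lists tested. The calls on members were counted over all genes tested and again adjusted over the list alone, and the counts were equal for every list. A list of quiescence and FOXO target genes and a list of simple epithelium genes were added after the data had been seen, before the values of most of their members were seen, and were adjusted as a pair.

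For seed sites, the longest annotated 3' UTR of at least 50 bases was taken for each gene from GENCODE release 21. It was searched for the 7-mer that pairs with bases 2 to 8 of the mature microRNA, ATCTAGT for miR-28-3p and AGCTCCT for miR-28-5p. The median log2 fold change of genes with the site minus that of genes without was ranked among the same difference for 1000 random 7-mers. These were drawn with a fixed seed from those held by a number of genes within 20% of the number with the site. Camera was run on the same sets. A first version took the 1000 7-mers nearest in number; it was replaced by the random draw that had been planned.

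Alternatives were DESeq2 1.42.0, limma-voom, other scalings in edgeR (DESeq2 size factors, upper quartile and total count), no filter, at least 10 CPM in 3 samples, and a minimum change of 1.5-fold. The replicate number was also used as a block, and each library was left out in turn. The deposited FPKM were analysed with limma-trend after adding a pseudocount of 1, 0.1 or 5. For lists, fry and camera with an estimated correlation were run, and for seed sites the 8-base site, the 7-mer with an A and the coding sequence. After the data had been seen, the scalings and the omission of the filter were extended to lists, seed sites and Lpp, and a setting was added in which a smooth trend of each library's log count on gene length and GC content, fitted with mgcv 1.9.3, was removed through offsets. Group means of library measures were compared with two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 libraries against 3. Ranking, windows along chromosomes and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

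The procedures were tested on simulated data. Over 11809 genes the edgeR test recovered 88% of genes changed by 1.5-fold and 91% of genes changed by 2-fold, and 7.25% of its calls were false, above the nominal 5%. The median fitted log2 change of the genes raised by 2-fold was 1.01. That simulation changed 100 genes by each fold and left the rest unchanged. In these data most genes differed, so its rates may not carry over. Camera called a set of 30 shifted genes and not a random set of 30, with genes drawn independently of each other, unlike real lists. Removal of a simulated length trend lowered the calls from 7563 genes to 29. Over 11648 genes the rank among matched 7-mers was 53.8 with no seed effect and 0 when site genes were lowered by 0.3 on the log2 scale. Nothing was left out of the 6 libraries. The mature microRNA, reads of the vector and sequence variants were not analysed here.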

Results

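The data are messenger RNA counts from PAM212 cells, labelled as mouse keratinocytes, in 3 libraries with lentiviral overexpression of miR-28-3p and 3 control libraries. The control libraries held 15385151, 14706283 and 15271490 counted reads, and the overexpression libraries 14309898, 15650640 and 16383374. Depth did not separate the groups (exact permutation p = 0.8). Other measures did so without overlap, each with the exact permutation p = 0.1 that is the smallest 3 against 3 can give. Ribosomal protein genes took 9.18 ± 0.0854% of the counts in the control libraries and 4.38 ± 0.0586% in the overexpression libraries. The 10 most abundant genes took 6.74 ± 0.0306% and 4.76 ± 0.0115%, and mitochondrial transcripts 2.08 ± 0.108% and 1.77 ± 0.0306%. Genes with any count numbered 13997 ± 21.9 in the controls and 13465 ± 74.5 with overexpression. The mean length of the gene behind a counted read was 5102 ± 14.9 bases in the controls and 6034 ± 14.7 bases with overexpression. No batch is given in the labels, so a batch that follows the groups cannot be told apart from the overexpression.

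The first question was what polyadenylated RNA shows of the miR-28 locus. The overexpressed gene was carried by the lentivirus, so the locus in the genome does not measure the overexpression. The mouse microRNA gene Mir28a lies on chromosome 16 at 24827855 to 24827940 on the plus strand of GRCm38. It sits in the intron between exons 8 and 9 of the Lpp-201 transcript of Lpp (ENSMUSG00000033306, chromosome 16, 24393507 to 24992578). The count table lists 0 microRNA genes, so only the host gene was measured. Lpp, which encodes an adhesion-site LIM protein, had 84.6, 78.1 and 83.8 CPM in the controls and 93.1, 96.4 and 90.8 CPM with overexpression. That is a log2 fold change of 0.19 ± 0.05 (SE derived from p, n = 3 against 3, edgeR adjusted p = 0.000173). Lpp was higher in each of the 3 overexpression libraries. The direction depends on the processing, since Lpp stood at -0.04 with upper quartile scaling, not called. It stood at -0.74 once a length and GC trend was removed, called lower. The level of the mature microRNA was not analysed here.

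The main question was which transcripts differ between PAM212 cells with and without miR-28-3p overexpression. Most tested genes differed. Genes of sterol and fatty acid synthesis, the cell cycle and the Hippo pathway rose, and interferon-stimulated, antigen presentation and ribosomal protein genes fell. In edgeR, 10159 of 11809 tested genes passed the adjusted p threshold, 4975 of them higher and 5184 lower with overexpression. The median size of the log2 fold change over all tested genes was 0.72. At least 2-fold changes were called for 1748 higher and 2483 lower genes, and at least 8-fold changes for 81 and 475. In 4984 genes (42.2%) every overexpression library lay above every control library, and in 5170 genes (43.8%) below, where chance gives 10% for both together. The spread between replicates was small, with a coefficient of variation, called biological in edgeR, of 2.93%, so that changes well under 1.5-fold passed the test. If the libraries of a group are technical repeats, this spread and the p-values leave out variation between cultures. Requiring a change beyond 1.5-fold left 5947 genes, 2762 higher and 3185 lower.

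The authors' deposited table gives 10020 genes with an adjusted p under 0.05, 4869 positive and 5151 negative. Of the genes called in it, 9679 were also called by edgeR in the same direction and 0 in the opposite direction. Across the 11809 genes tested in both, the median difference of log2 fold change was -0.01.

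The largest rises included 3 prolactin-family genes, Idi1 and Hsd17b7. Idi1 (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451), the isopentenyl diphosphate isomerase, rose 39.4-fold, from 3.88 ± 0.237 to 153 ± 3.55 CPM (SD, n = 3). Its log2 fold change was 5.30 ± 0.33 (SE derived from p, edgeR adjusted p = 2.76e-56). Hsd17b7, which acts in the later steps of cholesterol synthesis, rose 22.1-fold to 90.3 ± 0.936 CPM. Ccn1 (chromosome 3, 145646976 to 145649981), a secreted matricellular protein and Hippo pathway target, rose 16.9-fold, from 21.6 ± 1.6 to 366 ± 9.54 CPM. Adam12, a membrane metalloprotease, rose 18.9-fold from 3.57 ± 0.178 to 67.4 ± 2.47 CPM. Mfsd2a, a lysophospholipid transporter, and Uprt, named for uracil phosphoribosyltransferase, rose 18.3-fold and 17.9-fold to 22 ± 0.822 and 22.8 ± 2.87 CPM. Lce1g, of the late cornified envelope family, rose 23.3-fold to 11.7 ± 1.2 CPM from a control level of 0.493 ± 0.414 CPM, and its log2 fold change of 4.54 became 5.29 without control replicate 3. Prl2c2 and Prl2c3 rose 48.0-fold and 45.4-fold to 5.51 ± 0.324 and 12 ± 0.927 CPM. Prl3d2 had 3 counts in the controls and 228 with overexpression, a ratio of 74.4 with an exact 95% interval of 25.1 to 363. These 3 genes belong to a family of close paralogs on chromosome 13, and how their reads were assigned among them is not given in the sources used here.

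The largest falls left few or no counts in the overexpression libraries. Krt15 (ENSMUSG00000054146, chromosome 11, 100131758 to 100135928), a keratin of basal keratinocytes, had 1005 counts in the controls (21.4 ± 0.959 CPM, SD, n = 3) and 0 with overexpression. It was at least 342-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 2.9e-35). Alpl (chromosome 4, 137741733 to 137796384), the tissue-nonspecific alkaline phosphatase, had 3460 counts against 2, a ratio of 1767 with an exact 95% interval of 489 to 14600. Ltf (chromosome 9, 111019271 to 111042767), which encodes the iron-binding defence protein lactoferrin, fell 298-fold from 308 ± 3.52 to 1.02 ± 0.271 CPM. Pigr, the receptor that carries polymeric immunoglobulin across epithelia, fell 325-fold from 46.1 ± 1.93 to 0.128 ± 0.126 CPM. Its fold rests on 6 counts with overexpression, and its log2 fold change of -8.34 became -9.22 without overexpression replicate 3. Dhrs3, a retinal reductase, fell 298-fold from 35.7 ± 0.881 to 0.118 ± 0.151 CPM. It rests on 5 counts with overexpression, and its log2 fold change of -8.22 became -9.78 without overexpression replicate 1 and -7.62 without replicate 3. Stra6, a receptor for retinol uptake, had 612 counts against 2, a ratio of 313 (interval 86.2 to 2587). Gabrp, a subunit of the GABA-A receptor, had 861 counts against 3, a ratio of 293 (100 to 1425). Zbp1, a sensor of Z-form nucleic acid, had 492 counts against 2, a ratio of 251 (69.2 to 2081). Nlrp10, of the NOD-like receptor family, had 273 counts against 1, a ratio of 279 (49.6 to 11060). The overexpression counts of Stra6 and Zbp1 came from replicate 3 alone and that of Nlrp10 from replicate 1, and without replicate 2 the fitted log2 fold change of Gabrp went from -7.94 to -8.77.

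**Figure D1:**
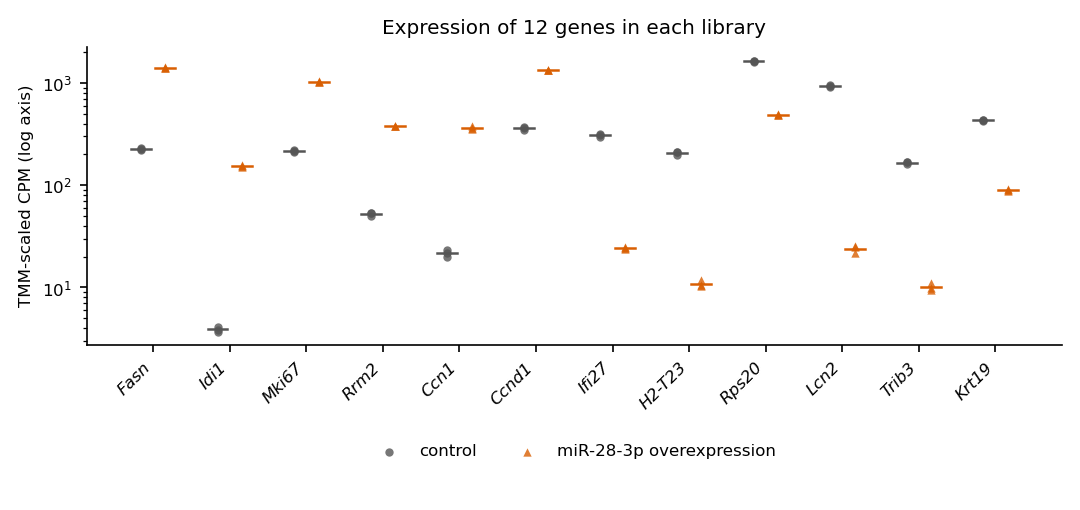
Expression of 12 genes in each of the 6 libraries, as TMM-scaled CPM on a log axis. Circles are control libraries and triangles miR-28-3p overexpression libraries, and bars mark the mean of n = 3. In each of these genes the 3 libraries of one group lie apart from those of the other, as in Fasn at 225 and 1410 CPM and in Lcn2 at 935 and 24.1 CPM.

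Lipid synthesis genes rose as a group. In the cholesterol biosynthesis list 23 of 23 tested genes rose and 0 fell, with 23 and 0 adjusted over the list alone, a median log2 fold change of 2.56 and a camera adjusted p of 1.62e-27. Cyp51, an enzyme of the sterol pathway, rose 13.7-fold from 25 ± 1.32 to 341 ± 5.48 CPM (SD, n = 3). In the fatty acid synthesis list 14 of 14 genes rose, likewise 14 adjusted over the list alone (median 1.16; camera adjusted p = 7.1e-13). Fasn, the fatty acid synthase, rose 6.26-fold from 225 ± 5.17 to 1410 ± 9.63 CPM. Fads2, a desaturase, rose 6.97-fold, Elovl6, an elongase, 5.26-fold, and Acly, which makes cytosolic acetyl-CoA, 3.92-fold.

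Cell cycle genes rose in both phases examined. In the G2/M list 30 of 30 genes rose (30 adjusted over the list alone; median 1.43; camera adjusted p = 4.21e-24). Mki67, the proliferation marker, rose 4.75-fold from 216 ± 3.24 to 1026 ± 11.6 CPM (SD, n = 3). Anln, which acts in cytokinesis, rose 5.11-fold, Ccna2, a cyclin, 5.73-fold, and Top2a, a DNA topoisomerase, 2.88-fold. In the G1/S list 28 of 30 genes rose and 1 fell, with 28 and 1 adjusted over the list alone (median 1.37; camera adjusted p = 2.34e-14). The ribonucleotide reductase subunits Rrm2 and Rrm1 rose 7.25-fold and 3.50-fold. The helicases Hells and Mcm4 rose 5.25-fold and 4.07-fold. Only 3 replication-dependent histone genes were tested, too few for the list test. All 3 fell (3 adjusted over the list alone), H1f2 from 41.6 ± 2.37 to 8.30 ± 0.531 CPM, H2bc4 from 6.90 ± 0.313 to 2.53 ± 0.276 CPM, and H1f3 from 0.935 ± 0.391 to 0.442 ± 0.433 CPM with an edgeR adjusted p of 0.0491. The call on H1f3 was lost without control replicate 1 (edgeR adjusted p = 0.278) and without overexpression replicate 2 (0.0811) or 3 (0.37). It was also lost without the filter (0.0661), against a 1.5-fold minimum (0.137) and in DESeq2 (adjusted p = 0.18). In FPKM with a pseudocount of 1, 0.1 or 5 it was lost too (limma adjusted p = 0.169, 0.108 and 0.231). The log2 fold change of H1f3, -1.13, became -2.01 without overexpression replicate 1 and -0.50 without replicate 3. Most such transcripts lack a poly(A) tail and are read incompletely in these libraries.

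Hippo pathway targets rose as well, 13 of 13 genes with 0 falling (13 adjusted over the list alone; median 1.47; camera adjusted p = 1.72e-09). Besides Ccn1, the transcriptional cofactor Ankrd1 rose 3.16-fold and the junction protein Amotl2 3.46-fold. Axl, a receptor tyrosine kinase, rose 2.77-fold from 468 ± 1.47 to 1297 ± 7.25 CPM (SD, n = 3).

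In the list of small RNA machinery 13 of 16 genes rose and 2 fell, with 13 and 2 adjusted over the list alone (median 0.74; camera adjusted p = 0.000989). Its call was lost with an adjusted p = 0.0508 with an estimated correlation and 0.207 after removal of the length and GC trend (range over 14 camera alternatives 0.000485 to 0.207). Xpo5, which exports microRNA precursors from the nucleus, rose 3.95-fold and Ago2, the slicing Argonaute, 3.45-fold. Dicer1, the enzyme that cuts precursors, and Cnot1, the scaffold of the deadenylase complex, each rose 2.49-fold. Of the heat shock genes 7 of 12 rose and 5 fell, with 7 and 5 adjusted over the list alone (median 0.19; camera adjusted p = 0.0299). This call was lost (adjusted p = 0.325 with an estimated correlation; range over 14 camera alternatives 0.00526 to 0.325), and the median turned to -0.04 with upper quartile scaling. The chaperones Hsp90aa1, Hspd1 and Hsph1 rose 3.01-fold, 3.09-fold and 2.59-fold, and Hspa8 fell 1.22-fold from 2721 ± 56.8 to 2231 ± 38.8 CPM (SD, n = 3).

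Interferon-stimulated genes showed the largest median fall of any tested list. There 32 of 34 genes fell and 1 rose, with 32 and 1 adjusted over the list alone (median -3.08, also with the 1 gene at 0 in a group set at its bound; camera adjusted p = 1.13e-12). Ifi27 fell 12.7-fold from 309 ± 10.4 to 24.3 ± 0.529 CPM (SD, n = 3). Rtp4 fell 34.9-fold, Oasl2 18.7-fold and Bst2, the tethering factor that holds back virus particles, 5.80-fold. In the antigen presentation list 16 of 17 genes fell and 1 rose, with 16 and 1 adjusted over the list alone (median -2.20; camera adjusted p = 2.43e-13). B2m, the light chain of class I molecules, fell 2.39-fold from 886 ± 12.7 to 371 ± 8.64 CPM. The class I genes H2-T23, H2-Q4 and H2-D1 fell 19.0-fold, 5.34-fold and 4.64-fold, although reads may be shared among such paralogs.

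Ribosomal protein genes fell, 39 of 40 with 1 rising and log2 fold changes from -1.75 to 0.25 (39 and 1 adjusted over the list alone; median -1.11; camera adjusted p = 1.51e-25). Rps20 fell 3.36-fold from 1642 ± 19.6 to 489 ± 3.55 CPM (SD, n = 3), and Rpl23, Rps9 and Rpl28 fell 2.88-fold, 2.58-fold and 2.68-fold. Short genes fell as a class in these libraries, and after removal of the length and GC trend 34 of 40 fell and 3 rose with a median of -0.60.

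Among the lists past the threshold downward were also those of the unfolded protein response, of autophagy and of glycolysis, each with members that rose. In the unfolded protein and integrated stress response list 15 of 25 genes fell and 6 rose, with 15 and 6 adjusted over the list alone (median -0.66; camera adjusted p = 6.31e-05). Trib3, a target of the integrated stress response, fell 16.4-fold from 166 ± 3.39 to 10.1 ± 0.829 CPM (SD, n = 3). Nupr1 and Ddit4, both induced by stress, fell 7.71-fold and 7.13-fold, and Hsp90b1, a chaperone of the endoplasmic reticulum, rose 2.04-fold. In the autophagy and lysosome list 18 of 22 genes fell and 4 rose, with 18 and 4 adjusted over the list alone (median -0.76; camera adjusted p = 6.38e-05), a call that was lost with an adjusted p = 0.0558 with an estimated correlation (range 1.1e-05 to 0.0558). Sqstm1, an autophagy receptor, fell 3.51-fold from 1620 ± 16.3 to 461 ± 13.6 CPM. Map1lc3b, a marker of autophagosomes, fell 2.96-fold, and the lysosomal proteases Ctsb and Ctsd fell 2.06-fold and 2.43-fold. In the glycolysis and hypoxia list 20 of 26 genes fell and 5 rose, with 20 and 5 adjusted over the list alone (median -0.54; camera adjusted p = 0.000516). The glycolytic enzymes Aldoc and Gpi1 fell 10.5-fold and 2.16-fold, and Ndrg1 and P4ha1, both induced by hypoxia, 2.77-fold and 2.72-fold.

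In all, 13 of the 29 lists tested passed the threshold, 7 upward and 6 downward. With an estimated correlation 10 of the 13 calls held, those lost being small RNA machinery, heat shock, and autophagy and lysosome. The calls that held did so narrowly, with camera adjusted p from 0.0151 for cholesterol biosynthesis to 0.0473 for G1/S genes. The far smaller camera values given above rest on the preset correlation of 0.01. By fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, 28 of 29 passed. Upper quartile scaling moved the median log2 fold change of all genes from -0.03 to -0.26, and list medians shift with it.

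**Figure D2:**
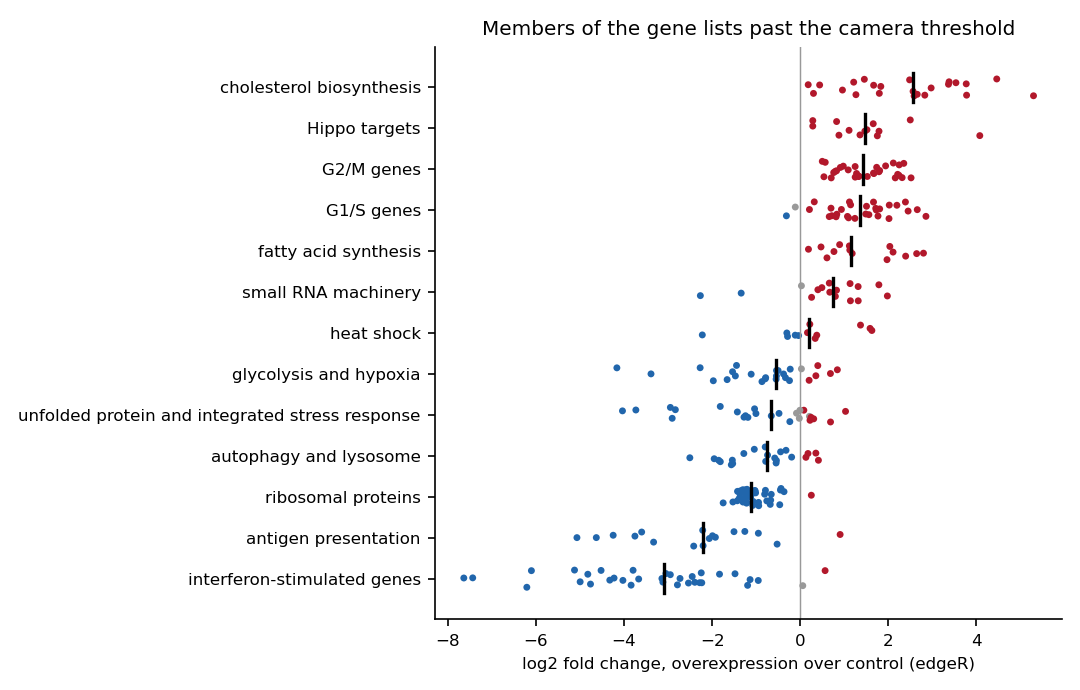
Log2 fold change, overexpression over control, of each tested member of the 13 gene lists past the camera threshold. Each point is a gene, red where it rose, blue where it fell and grey where edgeR did not call it, and black bars are list medians, from -3.08 for interferon-stimulated genes to 2.56 for cholesterol biosynthesis. The heat shock median changes sign with upper quartile scaling.

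Lists on the identity of the cells went in both directions. In the basal keratinocyte list 10 of 19 genes rose and 7 fell, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.211). Its median was 0.36 and its mean -0.40 with Krt15 at its bound, so they differ in sign. The laminin-receptor integrin genes Itga3, Itga6 and Itgb1 rose 2.11-fold, 2.37-fold and 1.72-fold, while Itgb4, a member of the list named here after its value was seen, fell from 197 ± 7.63 to 141 ± 3.49 CPM, and Dst, which links keratin to hemidesmosomes, rose 2.76-fold. In the keratinocyte differentiation list 7 of 11 tested genes fell and 1 rose, with 7 and 1 adjusted over the list alone (median -1.23; camera adjusted p = 0.211). Krt13, a keratin of stratified mucosa, fell 121-fold from 22.5 ± 1.56 to 0.180 ± 0.157 CPM (SD, n = 3). Sbsn, the envelope protein gene Evpl and the transcription factor gene Klf4 fell 4.23-fold, 2.34-fold and 1.79-fold. In the cell junctions list 14 of 24 genes fell and 10 rose, with 14 and 10 adjusted over the list alone (median -0.42; camera adjusted p = 0.154). Epcam and Cldn4 fell 2.64-fold and 2.52-fold and the plakoglobin gene Jup 2.60-fold, while Tjp1, which encodes ZO-1, rose 2.64-fold. In the mesenchymal transition list 7 of 17 genes fell and 5 rose, with 7 and 5 adjusted over the list alone (median -0.02; camera adjusted p = 0.52). There Fn1 fell 1.61-fold from 4075 ± 71.3 to 2524 ± 30.5 CPM, Mmp9 fell 2.01-fold, and Tnc rose 8.36-fold.

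Signalling and stress lists that did not pass the threshold also held strong changes in both directions. Of the p53 targets 11 of 22 rose and 11 fell, with 11 and 11 adjusted over the list alone (median -0.06; camera adjusted p = 0.495). Gadd45a and Trp53inp1 fell 20.7-fold and 12.3-fold, and Aen and Plk2 rose 5.66-fold and 2.87-fold. Of the inflammatory mediators 13 of 25 rose and 12 fell, with 13 and 12 adjusted over the list alone (median 0.08, mean -0.24; camera adjusted p = 0.875). Their median and mean differ in sign, and the median turned to -0.15 with upper quartile scaling, to -0.02 with total count scaling and to -0.33 without the length and GC trend. Ptgs2, the inducible cyclooxygenase, rose 10.7-fold from 67.6 ± 5.87 to 725 ± 4.66 CPM (SD, n = 3), and Ptges, a prostaglandin E synthase, fell 12.5-fold. Lcn2, a siderophore-binding protein, fell 39.0-fold from 935 ± 20 to 24.1 ± 1.93 CPM, and the cytokine gene Il24 rose 11.9-fold. In the EGFR and growth factor signalling list 14 of 23 genes rose and 6 fell, with 14 and 6 adjusted over the list alone (median 0.27; camera adjusted p = 0.677). With upper quartile scaling 9 rose and 10 fell. The ligand genes Hbegf and Nrg1 rose 2-fold and 3.58-fold, the feedback inhibitor gene Errfi1 rose 1.83-fold, and Spry1, also a feedback inhibitor, fell 2.66-fold. Of the immediate early genes 8 of 16 fell and 6 rose, with 8 and 6 adjusted over the list alone (median -0.40; camera adjusted p = 0.52), among them Junb and Jund, which fell 2.46-fold and 2.93-fold, and Klf6 and Myc, which rose 1.97-fold and 1.64-fold.

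Of the TGF-beta and BMP targets 7 of 13 fell and 2 rose, with 7 and 2 adjusted over the list alone (median -0.48; camera adjusted p = 0.325). Ccn2 rose 5.66-fold, and Id2, Pmepa1 and Ltbp2 fell 4.88-fold, 1.71-fold and 1.67-fold. Of the Wnt targets 4 of 8 fell and 3 rose, with 4 and 3 adjusted over the list alone (median -0.42; camera adjusted p = 0.79, direction up, opposite in sign to the median). Ccnd1 and Znrf3 rose 3.73-fold and 2.07-fold, and Notum and Lef1 fell 20.6-fold and 11.7-fold. In the Notch pathway list 6 of 12 genes rose and 3 fell, with 6 and 3 adjusted over the list alone (median 0.11, mean -0.16; camera adjusted p = 0.875). The receptor genes moved apart, Notch2 rising 1.89-fold and Notch3 falling 17.4-fold (log2 fold change -4.12, and -4.72 without overexpression replicate 3), while the ligand gene Jag1 rose 2.49-fold and Lfng, a modifier of the receptors, fell 2.59-fold. The list median turned to -0.12 with upper quartile scaling. Of the NRF2 targets 11 of 21 fell and 8 rose, with 11 and 8 adjusted over the list alone (median -0.38; camera adjusted p = 0.306). Aldh3a1, Slc7a11 and Gsta4 fell 30.7-fold, 7.50-fold and 7.12-fold, and Txnrd1 rose 2.07-fold. Without the length and GC trend the medians of the immediate early and NRF2 lists turned to 0.35 and 0.09. In the extracellular matrix and proteases list 14 of 27 genes fell and 12 rose, with 14 and 12 adjusted over the list alone (median -0.11; camera adjusted p = 0.443). Col18a1 fell 2.40-fold, and Col4a1 and the protease gene Adamts1 rose 1.89-fold and 12-fold. Of the mitochondrial transcripts 6 of 11 fell and 2 rose, with 6 and 2 adjusted over the list alone (median -0.50; camera adjusted p = 0.52). There mt-Cytb, mt-Co1 and mt-Co2 fell 1.40-fold, 1.22-fold and 2-fold, and mt-Nd1 rose 1.33-fold.

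Markers of keratinocytes and of other cell types were examined, since the identity of the line rests on its labels. Krt14, a basal keratin, was at 30.5 CPM in the controls and 39.1 CPM with overexpression, but its partner Krt5 had 0 counts in every library, as did Krt6a, Krt6b, Krt1, Krt2 and Krt4. Trp63, which encodes p63, a regulator of basal keratinocytes, fell from 1.13 ± 0.259 to 0.110 ± 0.191 CPM (SD, n = 3; edgeR adjusted p = 9.81e-06), with its overexpression counts in replicate 2 alone. These marker genes were singled out after their values were seen. Of 41 listed keratinocyte differentiation genes, 29 were under 1 CPM in every library and 18 had no count. Of 23 basal keratinocyte genes, 4 were under 1 CPM in every library, 3 of these with no count, and 9 were over 100 CPM in every library. Krt8 and Krt18, the keratins of simple epithelium, were at 1239 and 1798 CPM in the controls and at 1088 and 1070 CPM with overexpression. Genes tested were too few for the list test in 3 marker lists. Of 3 melanocyte markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), Pmel and Mitf falling 2.18-fold and 1.44-fold and Slc24a5 rising 1.71-fold, all from levels of 7.02 CPM or less. The call on Slc24a5 was lost without control replicate 1 (edgeR adjusted p = 0.109) or overexpression replicate 1 (0.0811), with upper quartile scaling (0.0598) and against a 1.5-fold minimum (0.175), and that on Pmel after removal of the length and GC trend (0.135). Of 3 fibroblast markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), with Pdgfra falling 2.75-fold from 44.9 ± 4.13 CPM (SD, n = 3), Col1a1 falling 12.8-fold from 2.67 ± 0.663 CPM and Fbn1 rising 3.82-fold to 1.90 ± 0.390 CPM. The log2 fold change of Fbn1 went from 1.93 to 2.83 without control replicate 1, and its call was lost in FPKM with a pseudocount of 5 (limma adjusted p = 0.0559). Of 2 immune cell markers 1 fell and 0 rose (1 and 0 adjusted over the list alone). Cd68, a lysosomal protein of macrophages also made by other cells, fell 4.20-fold from 19.1 ± 1.83 CPM, and Csf1r, the macrophage growth factor receptor, was at 0.818 ± 0.379 and 0.811 ± 0.190 CPM. Among keratinocyte factors directed at melanocytes 6 of 12 rose and 5 fell, with 6 and 5 adjusted over the list alone (median 0.28, mean -0.53; camera adjusted p = 0.925), and the median turned to -0.02 without the length and GC trend. F2rl1, the receptor that drives melanosome uptake, rose 3.03-fold from 25.3 ± 0.491 to 76.9 ± 2.93 CPM, and Lif rose 1.75-fold.

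A microRNA lowers messages that pair with its seed, so genes with miR-28-3p sites were set against the others. They were higher with overexpression, not lower. The 757 tested genes with a 3' UTR match to bases 2 to 8 of miR-28-3p (ATCTAGT) had a median log2 fold change of 0.36, against -0.05 for 10891 genes without. The difference was 0.41 (camera adjusted p = 0.000796 over the sites of both arms). Of the site genes 442 (58.4%) rose and 205 (27.1%) fell, against 41.2% and 44.9% of the genes without the site. Matched 7-mers gave a median difference of 0.28, with 5th and 95th percentiles of 0.10 and 0.42, and the miR-28-3p site lay at percentile 93.2. After removal of the length and GC trend the difference was 0.07 (camera adjusted p = 0.909), which ends the camera call, while its percentile among the matched 7-mers was 96.3, just above their 95th percentile of 0.07. Over 17 alternatives the difference ranged from 0.07 to 0.57. For the miR-28-5p site, from the other arm of the hairpin, the difference was 0.16 over 1837 genes, at percentile 25.4 (camera adjusted p = 0.118). With an estimated correlation both sites passed in the upward direction, each with an adjusted p = 0.00315 with an estimated correlation.

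**Figure D3:**
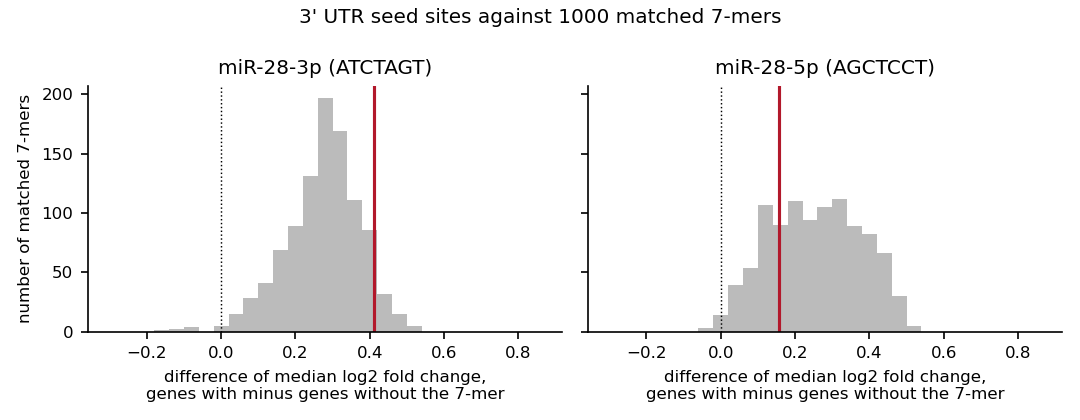
Difference of the median log2 fold change between genes with and without a 3' UTR 7-mer, for 1000 random 7-mers held by a similar number of genes (grey, number of 7-mers) and for the miR-28 sites (red lines). The miR-28-3p site stands at 0.41, at percentile 93.2, and the miR-28-5p site at 0.16, at percentile 25.4, and the dotted line marks 0.

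Genes with a miR-28-3p site that fell were led by H3f3b, which encodes the histone variant H3.3. It fell 2.15-fold from 1778 ± 13.6 to 825 ± 19.8 CPM (SD, n = 3), and its site lies in the 3' UTR on chromosome 11 at 116022601 to 116022607. Atf5, a stress-regulated transcription factor, fell 10.8-fold from 107 ± 0.955 to 9.92 ± 1.26 CPM, with its 3' UTR site on chromosome 7 at 44812311 to 44812317. Smim14 fell 4.51-fold and has 2 sites in its 3' UTR on chromosome 5, at 65448326 to 65448332 and at 65447601 to 65447607. Ube2h, a ubiquitin-conjugating enzyme, fell 3.18-fold, with its 3' UTR site on chromosome 6 at 30211400 to 30211406. Genes in the literature as targets of miR-28 formed a list of their own, of which 10 of 13 tested rose and 3 fell, with 10 and 3 adjusted over the list alone (median 0.42; camera adjusted p = 0.0615). This list was not divided by arm of the hairpin, and the arms differ in seed. Its direction therefore does not test targets of miR-28-3p alone. The list passed without control replicate 3 (adjusted p = 0.0411) and without the filter (adjusted p = 0.0398), and ranged up to 0.32 over the camera alternatives. Ccnd1, a G1 cyclin, rose 3.73-fold from 361 ± 11.2 to 1346 ± 8.03 CPM, Mad2l1, of the spindle checkpoint, rose 2.53-fold, while Nfe2l2, which encodes NRF2, fell 1.92-fold.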

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

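The removal of a length and GC trend was chosen after the data had been seen. So were the scalings and the omission of the filter for lists and seed sites, every Lpp setting but total count scaling, the block and left-out libraries, and for named genes the filters, limma-voom, the 1.5-fold minimum and the FPKM values. The number of genes called stayed between 8427 and 10679 over the scalings, filters, tools, the FPKM values and the block, and between 10016 and 10118 when each library was left out in turn. A minimum change of 1.5-fold was the exception, with 5947 genes, 2762 higher and 3185 lower, since it tests against a larger change. The split between directions followed the scaling, from 49% higher with TMM to 38.6% with upper quartile scaling, which moved the median of all genes from -0.03 to -0.26. After removal of the length and GC trend 9988 genes were called, of which 8134 were called in the same direction before and 854 in the opposite one. Whether the numbers in the titles pair the samples is not given in the labels. Correlations of residuals between libraries of the same number were 0.014, 0.023 and -0.002. They show no sign of pairing but cannot exclude it. With the number as a block 10116 genes were called.

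Of 29 lists 13 passed, 10 to 14 over the camera alternatives and 28 by fry, which does not compare a list with other genes. With the block 12 lists passed. The heat shock list was lost with upper quartile scaling (adjusted p = 0.079), without the filter (0.147), at 10 CPM or more (0.0649) and with the block (0.136), besides the estimated correlation, and the cause was not tested. The list of published targets passed without the filter and without control replicate 3, and the cause was not tested.

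Lpp, the host gene of miR-28, depended on the processing. Its log2 fold change of 0.185 turned to -0.044 with upper quartile scaling, where it was not called. Without the length and GC trend Lpp stood at -0.740 and passed the threshold as lower. It kept its direction without passing the test at 0.092 with total count scaling, at 0.089 in genes of at least 10 CPM, at 0.185 against a 1.5-fold minimum, and at 0.075, 0.091 and 0.041 in FPKM with a pseudocount of 1, 0.1 and 5. Its range without each library was 0.151 to 0.213, and with the block it was 0.186. The cause was not tested.

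The seed-site difference lay between 0.397 and 0.414 without each library, at 0.413 with the block and at 0.506, 0.385 and 0.567 for the 8-base site, the 7-mer with an A and the coding sequence. It fell to 0.074 without the length and GC trend, since that setting removes whatever part follows gene length and GC content.

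Of the 152 named genes other than Lpp, 142 kept their direction and side of the threshold in every alternative that tested them, and 5 more lost the call only at the 1.5-fold minimum. Between 150 and 152 of the named genes were called with each library left out, and at least 10 CPM in 3 samples left 14 of them untested. Csf1r, not called and near 0.8 CPM, changed sign to 0.005 without the filter, 0.089 without the trend and 0.050 in limma-voom, and ranged from -0.222 to 0.418 with each library left out, as its 38 and 36 counts allow. Depth limits genes under 0.21 CPM, the level of 3 counts in the smallest library, and folds of genes with 0 to 3 counts in a group, which are given as bounds or intervals.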

Other observations

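The 2 gene lists below, the removal of a length and GC trend, the share of variance between windows and the need for the window value to hold without that trend were chosen after results had been seen, as were the melanocyte genes singled out. Genes of resting cells and FOXO targets fell with overexpression. Of 17 tested genes 15 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.84; camera adjusted p = 1.2e-05, and adjusted p = 0.0145 with an estimated correlation). Pnrc1, a nuclear receptor coactivator, fell 4.78-fold from 237 ± 4.16 to 49.7 ± 3.79 CPM (SD, n = 3). Sesn3, a stress-induced inhibitor of mTORC1 signalling, fell 3.25-fold, Fbxo32, a ubiquitin ligase subunit known from muscle wasting, 6.89-fold, and Btg1, which restrains proliferation, 1.6-fold.

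Genes of simple epithelium, the single-layered kind, fell as a list, although PAM212 is labelled a keratinocyte line. Of 18 tested genes 14 fell and 3 rose (14 and 3 adjusted over the list alone; median -0.92; camera adjusted p = 1.2e-05, and adjusted p = 0.0145 with an estimated correlation). Krt19, a keratin of simple epithelium, fell 4.82-fold from 433 ± 5.85 to 89.9 ± 1.17 CPM (SD, n = 3), and Spint2, a protease inhibitor, fell 2.25-fold. The 3 that rose were Cdh1, which encodes E-cadherin, Cd24a and Grhl2, by 1.39-fold, 1.34-fold and 1.43-fold. Without the length and GC trend 11 fell and 6 rose, with a median of -0.35. Krt7 was at 1174 ± 13.4 and 1163 ± 14.5 CPM and was not called.

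Reads of pigment genes appeared at low counts in the overexpression libraries, and whether they come from the cells, from carry-over or from reads assigned to the wrong library was not tested. Tyrp1, which encodes a melanosomal enzyme, had 0 counts in each control library and 7, 18 and 15 counts with overexpression. Dct, another enzyme of melanin synthesis, had 0 in each control library and 10, 8 and 13 with overexpression, and Trpm1, a cation channel, had 0 and then 4, 4 and 3. Pmel went the other way, with 87 counts in the controls and 38 with overexpression, and Tyr had 0 counts in all 6 libraries.

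The first pattern weighed is the breadth of the change, 10159 of 11809 genes. Direct repression across the genes with miR-28-3p sites as its cause is argued against by the rank of the site. That was percentile 93.2 among matched 7-mers (96.3 without the length and GC trend), where such repression would put it under the 5th. The simulated lowering of site genes was 0.3 on the log2 scale, and a weaker lowering was not tried. The rank does not cover changes downstream of a few repressed targets, which remain open. A length and GC trend exists, with Spearman correlations across genes of 0.33 with length and -0.32 with GC content (genes are not independent replicates). After its removal 80.1% of the calls stood in their direction, which argues against it as the whole cause, though with 854 genes turned. That is only just past a limit of 80%, which was set before this test was run but after other results had been seen. The median size of the medians over windows of 50 neighbouring genes was 0.232 against at most 0.141 in 1000 shuffles (0.132 against 0.131 without the trend). A difference in DNA copy number may contribute to this. Neighbouring genes that move together for another reason would also exceed the shuffles, so these cannot tell the 2 apart. The window that holds Krt15, Krt13 and Krt19 had a median of -0.738 over its 50 genes. It was not the most extreme, as a window on chromosome 7 stood at -1.031. Such medians do not show why the genes of a window moved together. With 5.06% of the variance between windows (1.63% without the trend), copy number is argued against as the whole cause. Copy number and composition both run in blocks along chromosomes, and a batch, a clonal difference or the response to the virus itself remains open as well, since each would follow the groups.

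The second pattern is the joint movement of sterol, cell cycle and interferon lists. A length and GC trend as its cause is argued against. With the trend removed, the largest camera adjusted p of the cholesterol, G2/M and interferon lists was 1.54e-13 at the preset correlation. A candidate explanation is a difference in growth state between the cultures, such as density or time since feeding. It needs the genes of resting cells to fall in the faster growing culture, and their median was -0.838. That list was added after the data, including the rise of the cell cycle lists, had been seen, so its fall is weak support. Txnip was left out of the list, and the list does not bear on the interferon genes. Of the ribosomal protein genes 39 of 40 fell and 1 rose, with a median of -1.11 (-0.60 without the trend). Faster growth does not call for that fall, so a difference in growth state does not cover every list. Whether such a state came from miR-28-3p or from how the cultures were handled remains open, and no density or passage is given in the sources used here.

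The third pattern is the near absence in every library of some keratinocyte genes, such as Krt5. It held for 29 of 41 keratinocyte differentiation genes but only 4 of 23 basal keratinocyte genes, all under 1 CPM in every library. Of the basal genes 9 were over 100 CPM in every library. Loss of keratin reads in mapping or counting is an unlikely cause, since Krt8 and Krt18 had at least 1030 CPM in each library. Reads of Krt5 or Krt6a lost to close paralogs alone remain open, as does the identity of the line, and no biological explanation was tested, since the absence is shared by both groups.

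With 6 samples there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10159 genes by edgeR and the highest other 0, with 2 to 10 genes at an unadjusted p under 0.05, so that 1 of the 10 splits gave as many genes. The real split gave 13 gene lists past the threshold and the highest other also 13, so that 2 of the 10 splits gave as many lists. The other splits ranged from 11 to 13 lists, so the number of lists hardly sets the real grouping apart from them. For the higher seed-site genes the real split gave a camera p of 0.000398. The others gave 0.000163 to 0.00191 under this permutation of the labels, so that 4 of the 10 splits gave a p as small. Each other split still sets 2 libraries of one group against 1 and so keeps part of the difference.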
